A study of Homo sapiens with 4 samples.

How the data were processed

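H3K9la ChIP-seq was used to map histone H3 lactylated at lysine 9 in KYSE30, an established cell line from an oesophageal squamous cell carcinoma. The labels list 4 samples, which are an anti-H3K9la ChIP library and an input library for each of the arms named sg3 and V2. What the names sg3 and V2 stand for is not given in the sources used here, so they are kept as names. Each arm has 1 ChIP library and 1 input library, so there are no replicates.

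Per the submitters' processing notes, reads were handled with FastQC 0.12.1, Trim Galore 0.6.10, Bowtie2 2.5.1, SAMtools 1.18 and MACS2 2.2.9.1, on genome build hg38. The deposited data are 2 peak lists in the narrowPeak layout of MACS2, with 1 list for each arm. The sg3 list is filed under the sg3 ChIP sample, and the V2 list is filed under the V2 input sample. The command line, the control library behind each list, the treatment of reads with several alignments and the read depth are not given in the sources used here. An IgG control is named in the series description, and IgG libraries were not analysed here. Each list was taken as called on 1 library.

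The fold enrichment of a record, a ratio of ChIP pileup to background at the summit, is the authors' value as MACS2 wrote it. The -log10 p and the -log10 q of a record are also the authors' deposited values, and the smallest -log10 q was 2.02 in the sg3 list and 2.009 in the V2 list. The integer score deposited by the authors equalled 10 times the -log10 q without its decimals in 99.98% of sg3 records and 99.82% of V2 records, so it was not used further. The other deposited column, the summit offset from the start of a record, was used by position only. Fold enrichment and -log10 q were used to describe, rank or filter regions within 1 list.

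Records of a list that overlapped were to be merged into regions. No records overlapped, so each record was 1 region. Regions of the lists were called shared when they overlapped by at least 1 base. As a description of random placement, the regions of each list were moved at random 100 times within their chromosomes or contigs, whose lengths were taken as the largest coordinate seen in the lists or the gene table. Assembly gaps were not excluded from this placement. Shares were given with exact Clopper-Pearson 95% confidence intervals, which cover counting error only. For a share of 0 the limit of 3 counts of the total was also given. With 1 library per arm, no test of the arms was made and no p-value was computed.

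Gene positions were taken from a RefSeq gene table of GRCh38.p14, the same build as the lists, with 19970 protein-coding genes on chromosomes 1 to 22 and X. All members of the gene lists matched this table by symbol. The table gives the lower and the higher coordinate of each gene without strand, transcripts or exons. The planned window of 1 kb around a transcription start site was therefore replaced by a window of 1 kb around either end of a gene, and the planned classes promoter, exon, intron and intergenic were replaced by gene end, gene body and outside protein-coding genes. A region was placed by its midpoint. A gene was counted when any part of a region lay within 1 kb of either of its ends. Random gene lists were to be matched on promoter GC content where a genome was given. They were drawn without that matching, as fixed for the case without a genome sequence.

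Before the data were examined, 12 functional gene lists and 5 lists of markers of other cell types were fixed, with the comparisons, the alternatives and the rule for named genes. The functional lists were glycolysis and lactate transport, TCA cycle and respiratory chain, cell cycle, squamous epithelium, mesenchymal state and migration, hypoxia and angiogenesis, sirtuins with histone deacetylases and acyl transferases, DNA repair, immediate-early and AP-1 factors with MYC, interferon response and antigen presentation, ribosomal proteins, and autophagy and apoptosis. The marker lists were those of liver, neuron, blood, muscle, and fibroblast and endothelium. The rule named SIRT3, LDHA, EP300 and VEGFA in every case. It also named, for each list, the 10 genes with the highest -log10 q at a gene end and no region of the other list within 5 kb of an end, and the 5 regions with the highest -log10 q. From each gene list it took up to 4 members, first those with a region in 1 list only and then those in both, by -log10 q. Some genes that this rule takes are not reported here. The sg3-only share of a gene list was placed among 10000 random lists of the same size drawn from the genes with a region in either list, and its coverage by a peak list among 10000 random lists drawn from all protein-coding genes.

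Alternatives changed the overlap that counts as shared, the threshold on -log10 q (5 or 10), the fold enrichment (4), the length of the lists (equal length, or the 5000 strongest regions), the merging distance (1 kb), the window at gene ends (2.5 kb), the point that places a region, and the contigs used. Matching of random lists on gene length (5 strata) or on the -log10 q of the sg3 region (10 strata), and leaving out contigs other than chromosomes for genes, were added after the data were seen.

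MACS2 computes fold enrichment and p from the ChIP pileup and the control background at the summit, so both were solved from each record. Pileups had to be whole reads within 0.02 after the scale of the library. A single solution was found for 97.5% of sg3 records and 98.1% of V2 records. In simulated lists of 4991 unscaled and 4997 scaled records, 96.15% and 98.1% were solved, and 100.0% of these returned the simulated pileup and background. Each simulated background was the lowest value or a whole multiple of the control scale. In the lists, 58.5% of sg3 and 56.1% of V2 backgrounds were such multiples, among low backgrounds above the lowest one. The simulation therefore does not cover the other backgrounds. The lowest background of a list, which MACS2 sets from the library total over the genome, served as its floor. These values were used in the closing observations, with 1000 bootstrap draws for intervals of median differences. Overlap was tested on shuffled regions against bedtools 2.31.1, and gene ends and percentiles were tested on planted regions and lists with known answers. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.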

Results

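H3K9la, the lactylated form of lysine 9 on histone H3, was profiled by ChIP-seq in KYSE30 oesophageal squamous carcinoma cells in 2 arms named sg3 and V2. The series title presents SIRT3, a sirtuin best known as a mitochondrial deacylase, as an eraser of this mark, and the arms pose the question of where H3K9la regions differ. Each arm has 1 peak list and no replicates, so every difference below compares 2 libraries and has no replicate check. Read depth is not stated in the lists. All fold enrichments and -log10 q values of regions are the authors' and rank regions within their own list.

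The sg3 list held more and wider H3K9la regions than the V2 list. It had 56875 regions covering 54.8 Mb, against 40332 regions covering 31.3 Mb in V2, a ratio of 1.41 in number and 1.75 in covered bases. The median width was 618 bases in sg3 and 560 bases in V2. Broad regions differed most, with 749 sg3 regions and 155 V2 regions of at least 5 kb. The strongest sg3 region lay on chromosome 5 from 42950873 to 42953645 (hg38), outside protein-coding genes, with a fold enrichment of 24.7 and a -log10 q of 212.5. The next was a 13670-base region inside TOM1L2, an adaptor protein gene, on chromosome 17 from 17925165 to 17938834. Regions whose nearest genes were IRGC, ANAPC1 and MPRIP came after it, with summits 15168, 124162 and 28023 bases from these genes. In the V2 list the strongest region lay on chromosome 1 from 175195571 to 175197568, 3948 bases from KIAA0040, with a fold enrichment of 39.8 and a -log10 q of 200.3. It was followed by regions whose nearest genes were RAP2B, OPA1, GPCPD1 and DLG1, at 22250, 132585, 43235 and 94980 bases from the summits. All 10 of these regions were shared between the lists. The count ratio was 1.27 when regions within 1 kb were merged and lay between 1.31 and 1.43 under thresholds on fold enrichment or -log10 q.

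Most V2 regions were also in the sg3 list, while the sg3 list had many regions of its own. Of the V2 regions, 34812 overlapped an sg3 region, which is 86.3% (95% CI 86.0 to 86.7%). Of the sg3 regions, 29794 overlapped a V2 region, which is 52.4% (95% CI 52.0 to 52.8%). Randomly placed regions overlapped the other list in 3.49% of cases for V2 and 2.34% for sg3. The bases covered in both lists came to 27.2 Mb, a Jaccard index of 0.461. Cutting both lists to 40332 regions brought the shared portions to 63.7% for sg3 and 76.7% for V2.

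Regions found in the sg3 list alone were weaker and narrower than the shared ones. The 27081 sg3-only regions had a median fold enrichment of 4.41 (interquartile range 3.63 to 5.49), against 5.76 (4.25 to 8.10) for shared sg3 regions. Their median width was 486 bases, against 843 bases. In the V2 list the 5520 regions without an sg3 partner had a median fold enrichment of 4.57 (3.72 to 5.51), against 5.35 (4.17 to 7.18) for shared ones. Sharing rose with strength in both lists. Among sg3 regions with a -log10 q of 20 or more, 85.6% were shared and 2642 were not. Among V2 regions of that strength 99.5% were shared and 61 were not. Each of the 3490 V2 regions with a -log10 q of 40 or more overlapped an sg3 region, and a count of 0 without a partner allows a share of up to 0.0860% (3 counts of the total), while the exact interval reaches 0.106%.

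**Figure D1:**
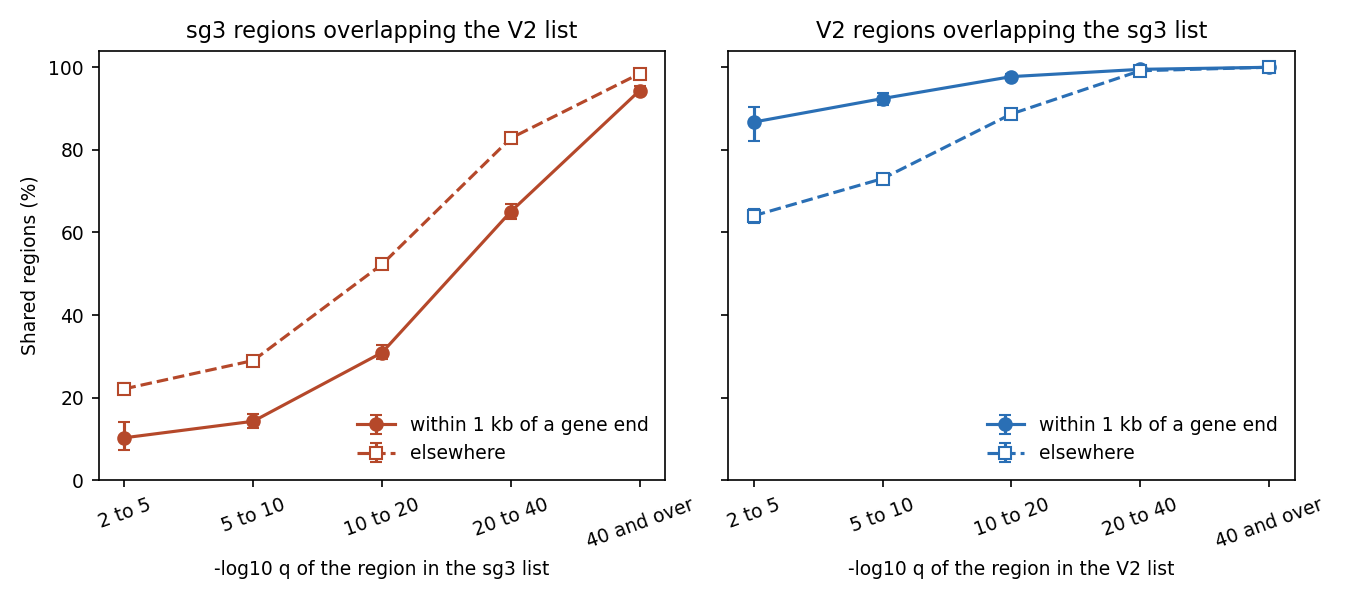
Share of H3K9la regions that overlap the other list (vertical axis, percent) by the -log10 q of the region in its own list (horizontal axis), for sg3 regions on the left and V2 regions on the right. Filled circles are regions with their midpoint within 1 kb of a protein-coding gene end, open squares are all others, and bars are exact 95% confidence intervals for counting error. At a -log10 q of 20 to 40, 65.1% of sg3 regions at gene ends and 82.8% of those elsewhere had a V2 partner.

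The ends of protein-coding genes carried H3K9la regions far more often than random placement gave, and they set the sg3-only regions apart from the V2-only ones. In the sg3 list 17.2% of regions (95% CI 16.9 to 17.5%) had their midpoint within 1 kb of a gene end, and in the V2 list 14.1% (95% CI 13.8 to 14.5%). Randomly placed regions did so in 2.68% and 2.75% of cases. Of the sg3-only regions 17.9% (95% CI 17.5 to 18.4%) lay at a gene end, whereas 182 of the 5520 V2-only regions did, which is 3.30% (95% CI 2.84 to 3.80%). With a window of 2.5 kb these became 25.8% and 9.24%. Gene bodies held 38.8% of sg3 regions and 39.4% of V2 regions, and 44.0% and 46.5% lay outside protein-coding genes.

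Stronger sg3-only regions were concentrated at gene ends. At a -log10 q of 20 or more, 1153 of 2642 sg3-only regions lay at a gene end, which is 43.6% (95% CI 41.7 to 45.6%), against 23.9% (95% CI 23.2 to 24.5%) of shared sg3 regions. Within the range from 20 to 40, 34.9% (95% CI 33.2 to 36.7%) of gene-end regions had no V2 partner, against 17.2% (95% CI 16.4 to 18.0%) of regions elsewhere. In the V2 list, the portions without an sg3 partner in that range were 0.498% (95% CI 0.215 to 0.980%) at gene ends and 0.844% (95% CI 0.633 to 1.10%) elsewhere, with overlapping intervals. In its range from 10 to 20 they were 2.26% and 11.3%. The gene table had no strand, so gene ends include both starts and 3' ends of genes. Regions were not matched on width in these comparisons, and a wide region that reaches a gene end can have its midpoint elsewhere.

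**Figure D2:**
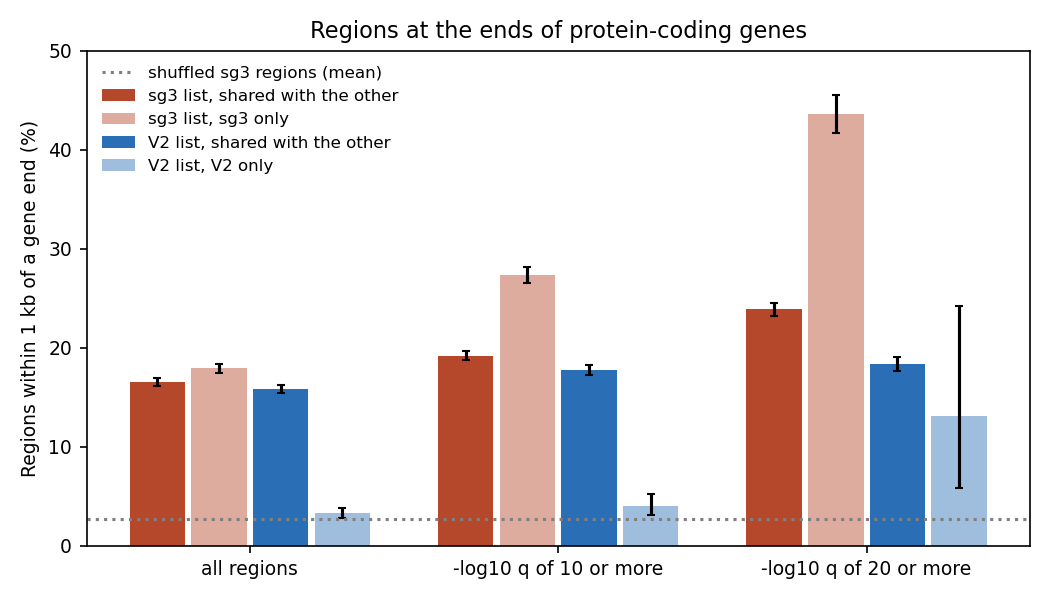
Share of H3K9la regions with their midpoint within 1 kb of a protein-coding gene end (vertical axis, percent), for all regions and for those with a -log10 q of at least 10 or 20 (horizontal axis), split into regions shared with the other list and regions of 1 list only. Bars on the columns are exact 95% confidence intervals for counting error, and the dotted line is the mean of 100 random placements of the sg3 regions (2.68%). The sg3-only share reaches 43.6% at a -log10 q of at least 20, and the V2-only share of all regions is 3.30%.

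Counted by gene, nearly every gene marked in V2 was also marked in sg3. Of 19970 protein-coding genes, 9424 had an sg3 region within 1 kb of an end, which is 47.2% (95% CI 46.5 to 47.9%), and 5741 had a V2 region, which is 28.7% (95% CI 28.1 to 29.4%). Both lists marked 5641 genes, where independent lists would give 2709. The sg3 list alone marked 3783 genes and the V2 list alone marked 100. The V2-only count depended on the settings, with 218 genes in lists of equal length and 54 when no sg3 region was allowed within 5 kb. The sg3-only count was 3028 in lists of equal length and 2965 when no V2 region was allowed within 5 kb.

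The SIRT3 gene itself (chromosome 11, 215030 to 236931) had a region at its higher-coordinate end in both lists. The sg3 region ran from 236761 to 237561 with a fold enrichment of 8.12 and a -log10 q of 39.2, and the V2 region from 236973 to 237469 with 4.56 and 12.6. PSMD13, a proteasome subunit gene, begins beside this end, so the regions belong to both genes. A region at a gene does not measure its expression and is no check of the arm labels. Fold enrichments are not comparable between the lists. Over shared regions at gene ends their median was 6.05 in sg3 and 4.54 in V2. LDHA, which encodes the lactate dehydrogenase subunit that favours lactate production, had 2 regions within 1 kb of its lower-coordinate end (18394563 on chromosome 11) in each list, from 18393344 to 18393869 and from 18394560 to 18395835 in sg3, and from 18393321 to 18393928 and from 18394605 to 18395372 in V2. The V2 region with the higher fold enrichment (6.12, against 5.75) was the one outside the gene, and in sg3 it was the one over the end (5.34, against 4.47). EP300, a histone acyltransferase gene, had nearly the same region in both, from 41091787 to 41093128 on chromosome 22 in sg3 (fold enrichment 8.95) and from 41091794 to 41093136 in V2 (6.62). VEGFA, the angiogenic growth factor gene, had a region from 43770724 to 43773280 on chromosome 6 in the sg3 list alone, with a fold enrichment of 3.75. The V2 list had its only region on this map past the gene, from 43799278 to 43799888 (5.32). It lay inside an sg3 region from 43799128 to 43800357, which had a fold enrichment of 9.07.

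**Figure D3:**
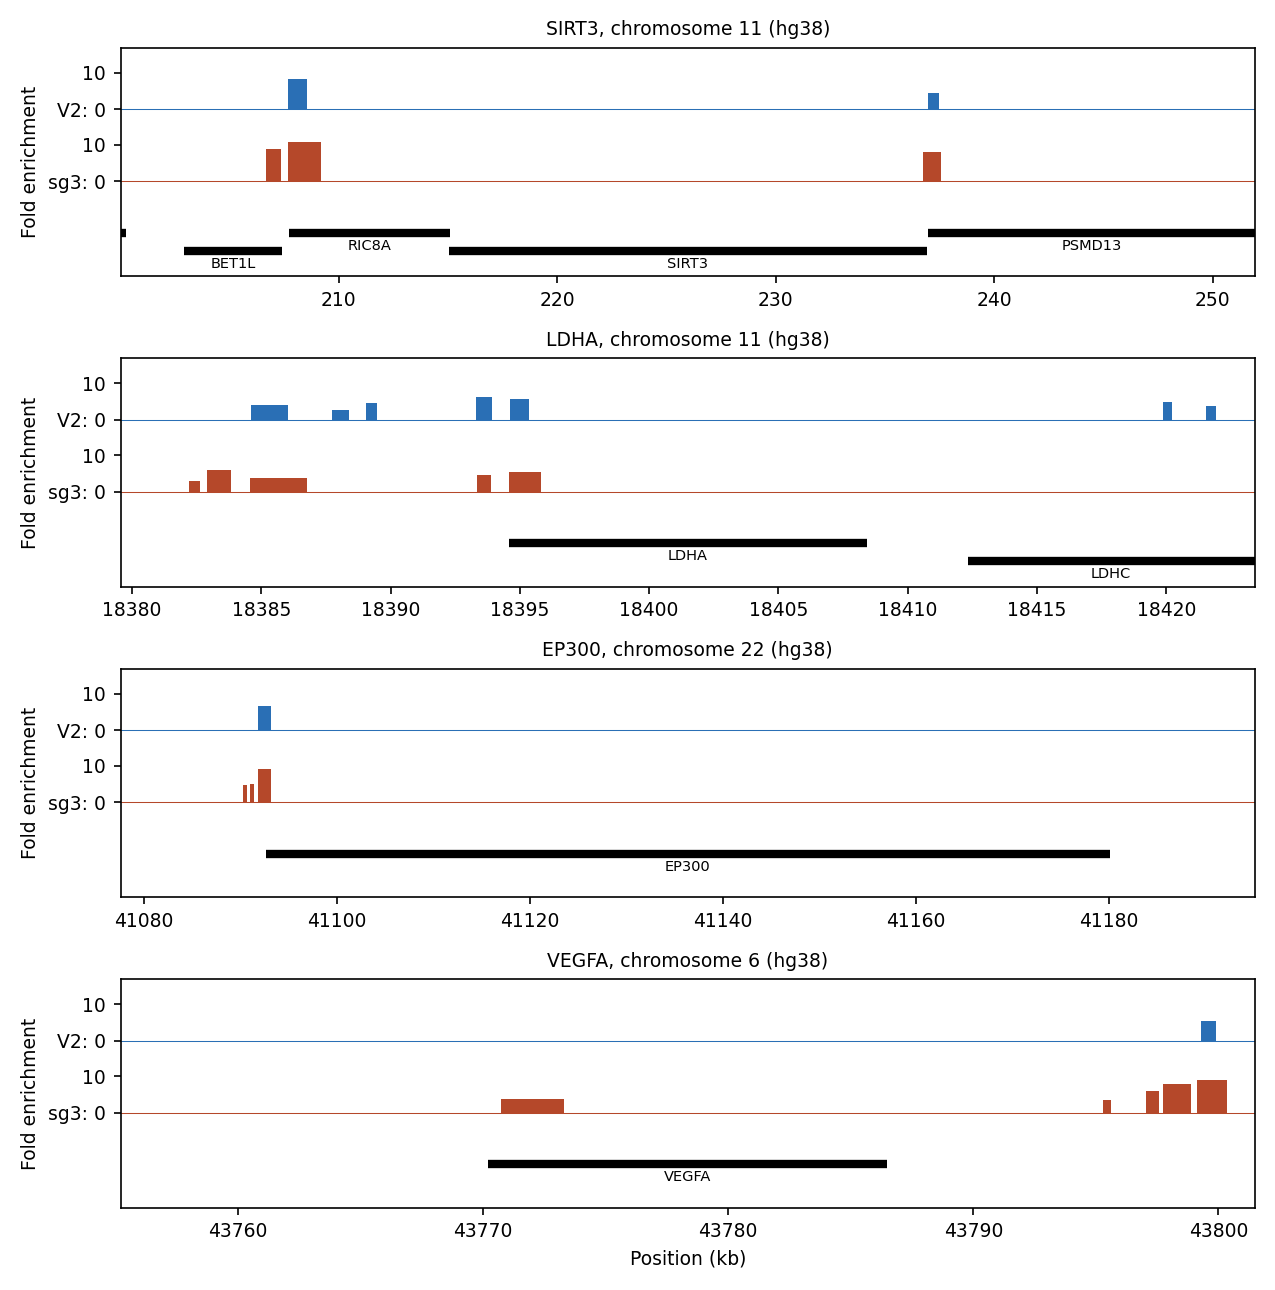
H3K9la regions around SIRT3, LDHA, EP300 and VEGFA in hg38 coordinates (horizontal axis, kb). Coloured blocks span each region and their height is the authors' fold enrichment in its own list (vertical axis, from 0), with V2 in blue above sg3 in red, and black bars are protein-coding genes. SIRT3, LDHA and EP300 have a region at a gene end in both lists, and VEGFA in sg3 alone.

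The genes with the strongest sg3 regions at an end and no V2 region within 5 kb were ZNF490 and ZNF791, neighbouring zinc finger genes that share the region from 12610935 to 12611455 on chromosome 19 (fold enrichment 11.5, -log10 q 78.7). SEC61G, a subunit of the endoplasmic reticulum translocon, followed with a -log10 q of 74.0 on chromosome 7 from 54758750 to 54759204. Its fold enrichment was 5.30, close to the median of 4.97 over all sg3 regions. GMNC, a regulator of multiciliated cells, followed with a -log10 q of 72.8 and a fold enrichment of 7.47. FKBP15 and the copper transporter gene SLC31A1 shared a region with a -log10 q of 70.6. BTBD10 had 66.1, SOS2, a RAS exchange factor gene, had 65.3, and CPB2 and ZC3H13 shared a region with 62.7. Among genes with a V2 region at an end and no sg3 region within 5 kb, RAB35, a membrane traffic GTPase gene, led with a -log10 q of 26.8 on chromosome 12 from 120116358 to 120116725. It was followed by SNRK with 25.6, WWP2 with 18.3, DOCK1 with 15.7, a region shared by LMNB2, TIMM13 and TMPRSS9 with 15.4, GLCCI1 with 14.4, HP1BP3 with 13.9 and NCOA1 with 13.4.

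Genes of the 12 functional lists were widely marked. Those in 1 list alone were nearly always in sg3, as they were over all protein-coding genes. Of all genes marked in either list, 39.7% were in sg3 alone and 1.05% in V2 alone. Of the 238 genes in the functional lists, 139 had a gene-end region in both lists, 62 in sg3 alone and 36 in neither. The V2-only gene was RPLP0, a ribosomal stalk protein, with a -log10 q of 6.99 in V2 and an sg3 region of 17.6 within 5 kb. It was named after its values were seen. Under alternative settings the count of V2-only genes in these lists ranged from 0 to 4, and that of sg3-only genes from 53 to 68. The 75 markers of other cell types were marked far less, with 10 in both lists, 2 in sg3 alone and 63 in neither. The sg3 list marked 84.5% of the functional genes and 16.0% of these markers, and the V2 list 58.8% and 13.3%.

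Genes of energy metabolism were largely marked in both arms. In glycolysis and lactate transport, 13 of 21 genes were marked in both lists, among them LDHA, and 4 in sg3 alone. These were PGK1 (fold enrichment 8.78), PFKM (5.68), PKM (5.42) and GPI (4.66), enzymes of the glycolytic chain. LDHB, HK1, ALDOC and ENO2 had no region within 1 kb of an end in either list. In the TCA cycle and respiratory chain list 13 of 20 were in both and 5 in sg3 alone, including MDH2 (8.10), NDUFA9 (10.3), SDHA (4.35) and OGDH (4.89). With a window of 2.5 kb the sg3-only count was 3. The sg3-only portions of these lists lay at percentiles 8.75 and 15.8 of random lists. Of the sirtuins with histone deacetylases and acyl transferases, 15 of 22 were in both lists, and SIRT7 (5.17), SIRT6 (4.34) and HDAC3 (2.89) were in sg3 alone, a count that was 5 at a -log10 q of at least 10. KAT8, a lysine acetyltransferase gene, had the strongest region of the shared members, with a fold enrichment of 12.2 in sg3 and 15.1 in V2. The V2 region lay across its higher-coordinate end, mostly past the gene. The sg3 region, of 7703 bases, ran past the same end, so these regions may not belong to KAT8 alone.

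Among the 12 functional lists, squamous and immediate-early genes were the most completely shared. In the squamous epithelium list 19 of 23 genes were marked in both lists, a low sg3-only share at percentile 0.510 of random lists and at 8.74 of lists matched on the strength of the sg3 region. The 3 sg3-only members were IVL, the cornified envelope protein involucrin (fold enrichment 10.8), TP63, the basal epithelial transcription factor (2.97), and KRT5, a basal keratin (4.98). Only the outer ends of each gene were searched, so regions further inside were not counted for any of these genes. NOTCH1, an epithelial differentiation receptor, was flanked by a 12724-base region in sg3 from 136546319 to 136559042 on chromosome 9 and a 12224-base region in V2. In the immediate-early and AP-1 list 14 of 15 genes were in both lists and none in sg3 alone (percentile 0.0750, and 5.78 with that matching). Its members with the highest -log10 q in the sg3 list were FOSB (12.8), IER2 (15.2), FOS (11.8) and JUNB (8.76), whose V2 regions had fold enrichments of 15.8, 11.0, 7.77 and 5.38 in that list. The sg3 value of FOSB is that of a 30308-base region reaching the gene. Its summit lay 3801 bases from ERCC1, the nearest gene, so the FOSB values of the lists belong to different sites. For JUNB (12791486 to 12793315 on chromosome 19) the sg3 region ran from 12777815 to 12793293 and the V2 region from 12788470 to 12791329. Both midpoints lay in the body of another gene, so these regions may not belong to JUNB alone.

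Cell cycle genes were evenly divided between both lists and sg3 alone, with 11 of 24 each. The sg3-only members included CCNB1, the mitotic cyclin B1 (fold enrichment 6.54), the mitotic kinase AURKB (5.79), and the cyclin-dependent kinases CDK4 (5.61) and CDK1 (4.70). Their portion lay at percentile 83.4 of random lists. Of the mesenchymal genes 7 of 20 were in sg3 alone, including the transcription factors ZEB1 (6.84) and SNAI2 (4.25), the integrin ITGA5 (3.68) and vimentin, VIM (3.13), and 3 were in sg3 alone in lists of equal length. Of the DNA repair genes 7 of 20 were in sg3 alone, including POLB (8.54), CHEK2 (6.01) and RPA1 (4.13). Of the ribosomal protein genes 8 of 20 were in sg3 alone, including RPL4 (8.28), RPL30 (6.32), RPLP1 (4.71) and RPL3 (6.68). Their portions lay at percentiles 70.6, 63.2 and 66.0.

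The remaining functional lists lay inside the bulk of random lists. In hypoxia and angiogenesis 6 of 16 genes were in both lists and 4 in sg3 alone, with a percentile of 51.6. These 4 were ADM (fold enrichment 5.55), VEGFA (3.75), EPAS1 (3.53) and P4HA2 (3.24). A V2 region with a -log10 q of 5.28 lay within 5 kb of an end of ADM. In the interferon and antigen presentation list 9 of 17 were in both and 4 in sg3 alone, including IRF9 (9.45), and PSMB9 with TAP1, neighbours that share a region (8.20), with a percentile of 27.3. In autophagy and apoptosis 13 of 20 were in both and 6 in sg3 alone, including ATG3 (7.93), APAF1 (5.19), SQSTM1 (3.64) and ATG5 (5.42), with a percentile of 24.3. Genes with near-identical copies, such as HLA genes, SDHA, CHEK2 and ribosomal protein genes, are reported as uncertain, since the treatment of reads with several alignments is not given in the sources used here.

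**Figure D4:**
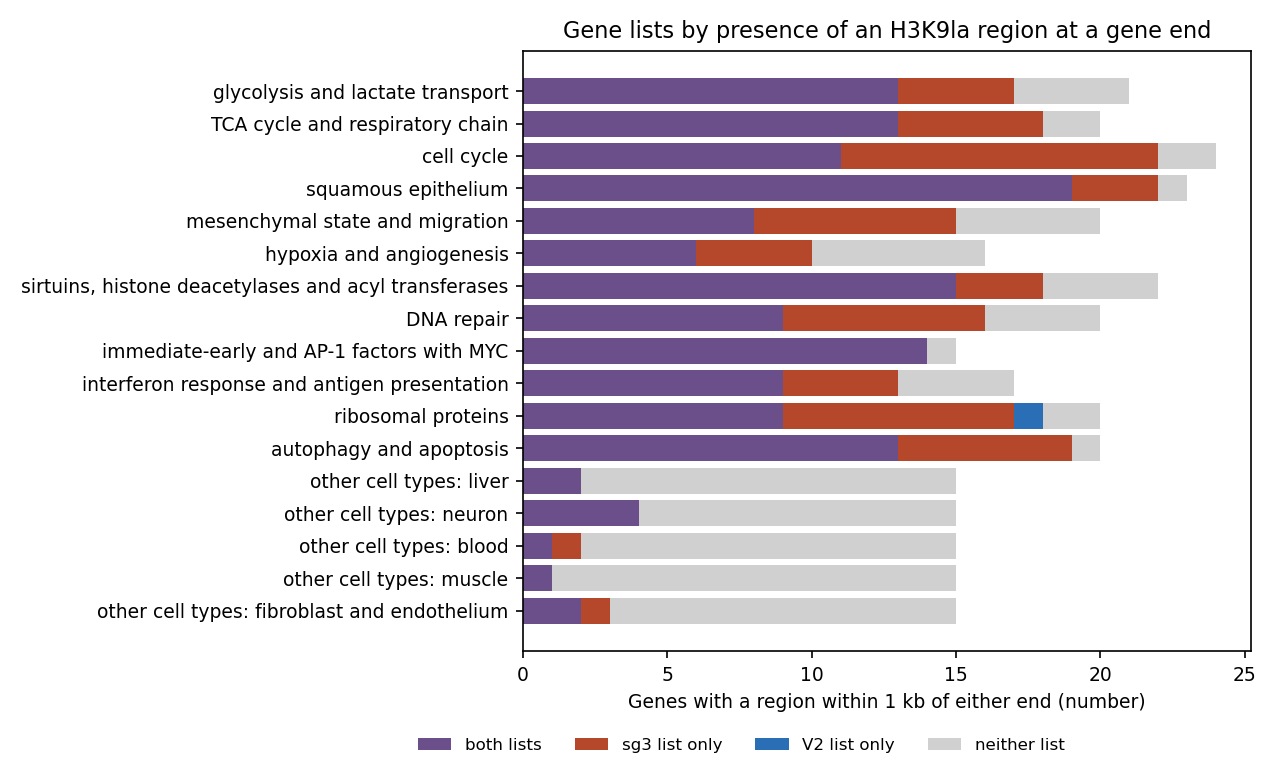
Number of genes (horizontal axis) with an H3K9la region within 1 kb of either gene end in both lists, in the sg3 list only, in the V2 list only or in neither, for each of 12 functional lists and 5 lists of markers of other cell types (vertical axis). Immediate-early and AP-1 factors have 14 of 15 genes in both lists, and the cell cycle list has 11 of 24 in both and 11 in sg3 alone.

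Markers of other cell types served as a background. Of 15 genes per list, 2 liver genes (TF and CYP2E1), 4 neuron genes (DLG4, TUBB3, SYT1 and RBFOX3), 1 blood gene (CD3D), 1 muscle gene (TNNT2) and 2 fibroblast and endothelium genes (COL1A1 and COL1A2) had a region in both lists. The sg3 coverage of these lists lay at percentile 0.390 of random gene lists for liver, 5.95 for neuron, 0.320 for blood, 0.0400 for muscle and 1.70 for fibroblast and endothelium. V2 coverage stood less far apart, at percentile 9.85 for liver, 44.3 for neuron, 2.60 for blood, 2.47 for muscle and 9.72 for fibroblast and endothelium. For liver, neuron and muscle the number of marked genes was the same in both lists. Their percentiles differ because V2 marked 28.75% of all protein-coding genes and sg3 marked 47.19%. Coverage of the functional lists lay at percentile 99.1 or higher in sg3, apart from hypoxia and angiogenesis at percentile 88.3. In V2 it ranged from percentile 77.8 for hypoxia and 85.4 for mesenchymal genes upwards. A region missing from a list is a region that did not pass the authors' threshold, and it does not show that the mark was absent.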

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

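The tests at matched summits, at equal strength, of the missing regions, of background away from gene ends and of pileup and V2 excess by tertile were chosen after the result was seen, while the test on control background within the sg3 list was written before its result. The control background that MACS2 used at each summit, which enters the fold enrichments and -log10 q values above but was not described there, was solved from the lists and was higher at gene ends. Among shared regions its median at gene ends was 1.53 times that elsewhere in the sg3 list (4.81 against 3.15 times the floor of the list) and 2.07 times in the V2 list (6.31 against 3.05). ChIP pileup over the floor was similar in the lists, at 31.5 for gene ends and 19.1 elsewhere in sg3, and 31.4 and 20.1 in V2.

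The pattern weighed first concerns sg3 regions at gene ends. In the -log10 q range from 20 to 40 they were missing from the V2 list by 17.8 percentage points more often than regions elsewhere. Width was not matched, and shared sg3 regions were wider than sg3-only ones (median 843 against 486 bases). A part of width in this difference therefore stays open. Unequal depth also stays open as an explanation, because control reads were 2.07 times ChIP reads in sg3 and 0.91 times in V2. These proportions need not act alike where control background is high. A candidate explanation, found from the difference in background above and so not tested independently of it, is a control library with more reads at gene ends in V2: at summits within 100 bases in both lists the V2 to sg3 log2 ratio of control background was higher at gene ends than elsewhere by 0.435 (0.415 to 0.452, 3816 and 17290 summits), and by 0.348 (0.317 to 0.386, 1572 and 4212 summits) at an sg3 -log10 q of at least 40. The test written beforehand, that gene-end regions of high sg3 background would be missing more often, gave the opposite: at a -log10 q of 10 to 20 the upper tertile was missing in 60.5% of cases and the lowest in 79.4%, a difference of -18.9 points (-23.0 to -14.6), with -34.0 points (-35.9 to -32.2) away from gene ends, but at a fixed q a higher background needs a higher pileup (median 60.0 reads against 32.0), so these values decide nothing on the control of either list, and neither does the V2 excess in control background, which rose from 0.32 in the lowest to 0.50 in the upper tertile of all matched gene-end summits. The log2 ratio of ChIP pileup differed between gene ends and elsewhere by -0.052 (-0.061 to -0.04) over all these summits and by 0.019 (-0.005 to 0.038) at the stronger ones, but summits called in both lists leave out the regions that were missing, for background as for pileup. The 4855 gene-end regions missing from V2 have no V2 pileup in the lists, so a loss of H3K9la there in the V2 arm and a control effect cannot be told apart.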

How the results depend on the processing

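Random lists matched on gene length or on sg3 strength, and the gene counts on chromosomes alone, were added after the data were seen. Of 145 alternative values other than percentiles, 96 stayed within the confidence interval or within 1.5 times the reported value, 49 moved and 0 reversed. Of 34 percentiles of gene lists under matching, 30 stayed on their side of 5 and 95, some of them after large shifts, and 4 did not. The shared portion of sg3 and of V2 regions was 43.7% and 84.6% with 50% of a region covered, 67.2% and 91.8% within 1 kb, 63.7% and 76.7% in lists of equal length, 63.1% and 75.6% for the 5000 strongest regions, and 67.6% and 94.4% for a -log10 q of at least 10 against all regions of the other list. With that threshold on both lists V2 had 86.9%. The lists held 35873 and 25105 regions at a -log10 q of at least 10, and 30783 and 24216 after merging within 1 kb. The gene-end portion of sg3 regions was 24.8% with a window of 2.5 kb, 17.6% by summit, 21.8% at a -log10 q of at least 10 and 20.7% at equal length, and that of V2 regions was 21.5% and 16.9% with the wider window and the threshold. For sg3-only regions it was 25.8%, 23.8% and 24.5% (window, threshold, equal length), and for V2-only regions 9.24% and 3.84% (window, equal length). Genes in V2 alone numbered 218 at equal length and 54 with sg3 empty within 5 kb, and those of the functional lists 0 with the wider window, 2 at the threshold and 4 at equal length. With 50% of a region covered, the median fold enrichment in sg3 was 5.69 for shared and 4.58 for other regions. Wider windows and the overlap rules move shares by construction, as thresholds and merging do for the number of regions, and for the rest the cause was not tested. Of 51 counts of sg3-only genes per gene list, 42 stayed the same or within 1.5 times, with 10 higher and 15 lower than reported. The planned comparison without matching of random lists equals the reported one, since no genome sequence was used, and was not run. No paired analysis was possible because each arm has 1 peak list. Depth, known only as ratios between the lists, limits all counts of missing regions.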

Other observations

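The matching on sg3 strength, and the tests of depth and of the input library were chosen after the data were seen, with the bounds for the gene lists written before their results, and the regions in the next paragraph were picked after their values were seen.

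The widest sg3 region spanned 30308 bases on chromosome 19 from 45439574 to 45469881, over the DNA repair gene ERCC1 and the lower end of FOSB. A region of 27706 bases overlapped MUC16, which encodes a mucin, on chromosome 19 from 9047816 to 9075521. Others of 27417 and 26308 bases on chromosome 1 had ELF3, an epithelial transcription factor gene, and IER5 as nearest genes, 38511 and 41409 bases from their summits, and 1 of 28570 bases on chromosome 2 had TEX44. In V2 the widest had 16219 bases on chromosome 19 from 13842424 to 13858642, with its summit 14011 bases from ZSWIM4. Next came a region of 15236 bases on chromosome 17, outside protein-coding genes. Its summit lay 24658 bases from the nearest gene, KRT17, a stress-induced keratin gene. Regions of at least 10 kb numbered 129 in sg3 and 17 in V2. Among regions of 1 list alone, SORBS2 held a strong sg3 region in its body on chromosome 4 from 185838015 to 185839204 (fold enrichment 19.6, -log10 q 72.2). The strongest V2-only region (-log10 q 32.3) lay outside protein-coding genes, with its summit 59963 bases from SMAD6, the nearest gene. The next ones lay at the lower end of CD109 (32.0) and in the body of RBPJ (31.2), a gene for a NOTCH pathway transcription factor.

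The sg3 excess was spread over the genome. Over 23 chromosomes the ratio of sg3 to V2 regions ran from 1.23 on chromosome 19 to 1.54 on chromosome 5, and the sg3-only portion from 43.0% to 51.5%. The second pattern weighed is this longer list. A V2 list called on the input library, under which it is filed, is argued against by its pileup: over the 7189 sg3 regions with a -log10 q of at least 40, of which 5784 had a V2 summit within 100 bases and the others were counted as lowest, the median V2 to sg3 log2 ratio of pileup over the floor was -0.11 (-0.12 to -0.10), where an input library was taken to lie lower by 1 log2 unit or more. Lower effective depth may add to it, since the background floor of V2 was 0.73 times that of sg3 and the solved depth of sg3 over V2 was 1.24 for ChIP and 2.83 for control reads, with 90.2% of sg3-only regions under a -log10 q of 20, but 2642 lay at or above 20 and 189 at or above 40. Depth and a difference in H3K9la between the arms cannot be told apart for this pattern, because each arm has 1 library and the lists give no reads outside regions.

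The third pattern weighed is the position of the gene lists. The sg3-only portion of cell cycle genes lay at percentile 60.2 of random lists matched on the -log10 q of the sg3 region and at 83.4 without matching, both between 10 and 90, so the matching decides nothing there. The low portion of immediate-early and AP-1 genes moved from percentile 0.0750 to 5.775 with matching, between the bounds of 2.5 and 10 set beforehand. This portion was 0, the lowest possible, and ties were counted at mid-rank, so a percentile under 2.5 could not occur. The matching therefore leaves open whether strength alone accounts for the low portion. The squamous list moved from percentile 0.510 to 8.74 and the sirtuin, deacetylase and acyl transferase list from 2.25 to 9.01, while the fibroblast and endothelium list, with 3 marked genes, moved from 43.4 to 4.98. No biological explanation was tested, since 1 library per arm leaves the arm and the library inseparable.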
